A study of Homo sapiens with 2 samples.

How the data were processed

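Total RNA was taken from 22Rv1 prostate cancer cells that expressed a control vector or a short hairpin RNA against EIF3F, 1 sample per group. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with an Illumina TruSeq RNA kit. The deposited values are TPM per gene, computed by the authors for each library and rounded to 2 decimals. CASAVA and HISAT2, without versions, and the genome build hg19 are named per the submitters' processing notes. The gene counter, the annotation, the use of strand and any filter are not given in the sources used here. The columns were matched to the groups by the sample descriptions.

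The table held 58884 gene entries for 57351 symbols. The 1533 entries that repeat a symbol were summed with their namesakes, and 27 entries whose symbols had been turned into dates by spreadsheet software (0.0336% of TPM in shCON and 0.0256% in shEIF3F) were left out, so the genes behind them are not analysed here. The 5740 symbols of small RNA genes (0.100% and 0.0601% of TPM) were left out because the library type recovers them poorly. Of all symbols, 56562 (98.7%) were found in GENCODE release 29, which was used for gene type, transcript GC content, transcript length and exon overlap. GC content and length are those of the longest annotated transcript of the gene's own type, which need not be the one expressed. That release describes GRCh38, whereas the notes name hg19, so no coordinates are given. TPM divides each library by its own total and keeps no read number, so depth is unknown and no counting interval or detection limit was computed. A value of 0 is given as listed at 0, with no fold: 64 of the genes tested were listed at 0 in shEIF3F and 84 in shCON.

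For each gene with a mean of 1 TPM or more over both libraries, the log2 ratio was log2((shEIF3F TPM + 1) / (shCON TPM + 1)), which understates the ratio of genes near 1 TPM. Genes at 1 or more, or at -1 or less, on that scale were counted as at least 2-fold higher or lower, a fixed rule of size and not a test. Across the genes tested the 2 libraries had a Pearson correlation of 0.854 and a Spearman correlation of 0.803 for log2 TPM, where genes are not independent replicates. For 42 gene lists (pathways, complexes and cell type markers), the median log2 ratio of members with a mean of 1 TPM or more was placed among the medians of 10000 random lists of the same size, matched on mean TPM in 20 bins. A list stood apart outside the central 95% of those medians, 2.5% at each end. Lists with fewer than 5 such members have member values only. The percentile describes these libraries and is not a p-value. A list whose genes share regulation spreads more widely than random genes do.

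The groups, the thresholds, the lists and the rule for named genes were set before the data were examined, as were alternatives with pseudocounts of 0.1 and 5, no filter on TPM or a mean of 5 TPM or more, ratios centred on the median of all genes, libraries rescaled without the 100 most abundant genes, small RNA genes kept, and the most abundant entry per symbol. The rule for named genes took EIF3F, every measured eIF3 subunit, the 15 genes with the highest and the 15 with the lowest log2 ratio at a mean of 5 TPM or more, and up to 4 members of each list with the largest absolute log2 ratio. Some genes and lists that were covered are not reported here. A gene named outside it is said to have been chosen after its values were seen. After the data were seen, removal of the GC or the length trend was added (ratios centred within 20 bins of transcript GC content, known for 99.1% of genes, or of length), as were counts over protein-coding genes and over genes with no shared exon, and a ranking of 12 such protein-coding genes at each end.

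The calculations were run in Python 3.11.15 with NumPy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. They were tested on simulated data for the shEIF3F and shCON comparison with 13311 genes: 6 of 100 unchanged lists of 30 genes lay outside the percentile limits, and 98 of 100 lists lowered by 1 on the log2 scale lay below percentile 2.5. With a GC trend removed, 200 simulated genes lowered by 1 had a median of -1.06.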

Results

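Gene expression was measured by RNA-seq in 22Rv1 cells, a castration-resistant human prostate cancer line. The cells carried either a vector control (shCON) or a short hairpin RNA against EIF3F (shEIF3F), which encodes the f subunit of translation initiation factor eIF3. Each group had 1 library and there were no replicates, so no difference given here has a replicate check and no p-value or error was computed. With 1 shEIF3F library, other effects of the hairpin cannot be told apart from those of EIF3F loss. Values are TPM, a transcript abundance normalised to transcript length and to the library total, summing to 992454 in shCON and 994055 in shEIF3F over the listed genes. TPM keeps no read number, so the depth behind each value is unknown. At 1 TPM or more, 13372 gene symbols were listed in shCON and 12583 in shEIF3F.

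The comparison asks which transcripts differed when EIF3F was depleted. EIF3F itself stood at 991 TPM in shCON and 17.0 TPM in shEIF3F, 1.72% of the control level (log2 ratio -5.78), in the direction the labels give. Among the other eIF3 subunits, EIF3H, EIF3M, EIF3L, EIF3E and EIF3D were at least 2-fold higher in shEIF3F. EIF3H, the subunit that forms a dimer with EIF3F in the complex, was highest in ratio at 158 and 474 TPM (log2 ratio 1.58), followed by EIF3M at 150.3 and 399.6 TPM (1.41). EIF3L had a log2 ratio of 1.23, EIF3E of 1.1 and EIF3D of 1.04. The RNA-binding subunit EIF3B was lower, at 169.9 and 35.6 TPM (-2.22), as was the scaffold subunit EIF3A at 19.1 and 8.55 TPM (-1.07), although EIF3A was less than 2-fold lower once ratios were centred on the median of all genes (-0.72). EIF3C, EIF3G, EIF3I, EIF3J and EIF3K differed by less than 2-fold. Over all 13 subunits the median log2 ratio was 0.16, at percentile 96.4 of random lists matched on expression, so the subunits did not stand apart as a set.

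**Figure D1:**
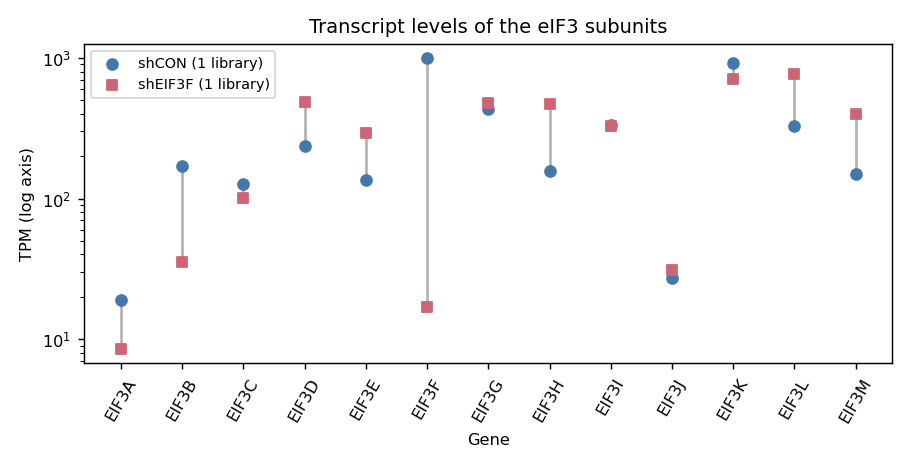
TPM of the 13 eIF3 subunit genes (log axis) in the shCON library (circles) and the shEIF3F library (squares), with a line joining the values of each gene. EIF3F goes from 991 to 17.0 TPM, while EIF3H goes from 158 to 474 TPM.

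Across the 13311 genes with a mean of 1 TPM or more, 3404 (25.6%) were at least 2-fold lower in shEIF3F and 1125 (8.45%) at least 2-fold higher. The median log2 ratio of all genes was -0.36. The 100 most abundant genes held 46.2% of TPM in shCON and 60.4% in shEIF3F. Centring the ratios on that median adds 0.36 to each, and rescaling the libraries without those 100 genes shifted the ratios by a median of 0.38. The genes at least 2-fold higher made up 24.8% of those past 2-fold in either direction as deposited, 47.9% after centring, 47.9% after rescaling and 48.8% with a GC trend removed. Centring and removal of the GC trend bring the split close to even by construction. Rescaling does not fix the split, but it makes the summed TPM outside those 100 genes equal in both libraries. A real overall fall among the other genes would thus be removed as well. The predominance of lower transcripts depended on scaling, and none of these steps shows which scaling is right. The median of each list that stood apart is given as deposited and relative to the median of all genes. Log2 ratios also went with transcript GC content (Spearman's rho -0.315 across 13195 genes, which are not independent replicates). The median was 0.072 among transcripts of about 36.5% GC and -1.15 among those of about 66.5% GC. Of 39 gene lists with enough measured members, 9 stood below and 9 above the central 95% of matched random lists, where chance alone would place 1.95 outside. With the GC trend removed, 11 stood below and 8 above, and 16 lists stood apart in the same direction both ways.

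**Figure D2:**
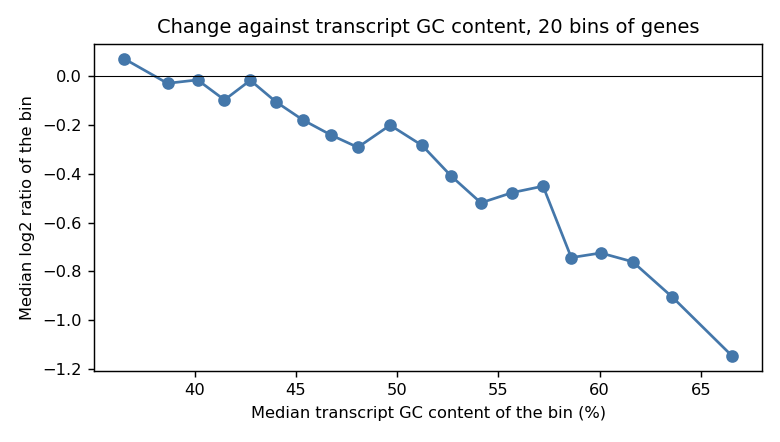
Median log2 ratio of shEIF3F over shCON (vertical axis) against median transcript GC content in percent (horizontal axis) for 20 bins of genes ordered by GC content, each point 1 bin. The median goes from 0.072 in the lowest bin to -1.15 in the highest.

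Genes of the cell division cycle had the lowest medians of the 39 lists. All 31 measured S phase genes and all 34 measured G2 and M phase genes were at least 2-fold lower in shEIF3F. Thymidine kinase TK1 stood at 234 TPM in shCON and 2.39 TPM in shEIF3F (log2 ratio -6.11), and CDC45, part of the replicative helicase, at 56.3 and 1.56 TPM (-4.49). Among mitotic genes, BIRC5, which encodes survivin, was at 127 and 1.32 TPM (-5.78), the ubiquitin-conjugating enzyme UBE2C at 281 and 6.38 TPM (-5.26), and CDC20, an activator of the anaphase-promoting complex, at 161 and 4.58 TPM (-4.86). The S phase median was -2.78 (members from -6.11 to -1.09) and the G2 and M phase median -3.40 (-5.78 to -1.02), both below all 10000 matched random lists. Relative to the median of all genes these were -2.42 and -3.04, with 27 and 33 members still at least 2-fold lower.

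Targets of p53 were higher. Of 26 measured, 9 were at least 2-fold higher, among them the cyclin-dependent kinase inhibitor CDKN1A at 90.5 TPM in shCON and 989 TPM in shEIF3F (log2 ratio 3.44), the secreted factor GDF15 at 25.9 and 229.7 TPM (3.10), and the ubiquitin ligase MDM2 at 13.7 and 44.5 TPM (1.63). The 2 members at least 2-fold lower were the pro-apoptotic genes BBC3 (-1.43) and BAX (-1.32), the latter chosen after its values were seen, and neither was past 2-fold with the GC trend removed (-0.28 and -0.58). The median was 0.67, or 1.02 relative to all genes, above all 10000 random lists. Regulators of apoptosis did not stand apart, with a median of -0.49 (percentile 37.7) and -0.13 relative to all genes. Replication-dependent histone genes had a higher median of 0.83 over the 10 of 22 members measured (1.19 relative to all genes, percentile 99.95). Of those measured, 5 were at least 2-fold higher and 4 within 2-fold. HIST1H2AC stood at 0.73 and 22.9 TPM (3.79), HIST2H2BE at 1.62 and 24.2 TPM (3.26) and HIST1H2BK at 18.5 and 98.4 TPM (2.35). These 3 genes are known to also give polyadenylated transcripts, unlike most of the family. The median rests in part on them, so it does not show that histone transcripts as a group went the other way from S phase genes. HIST1H4H was the only measured member at least 2-fold lower (-1.75).

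**Figure D3:**
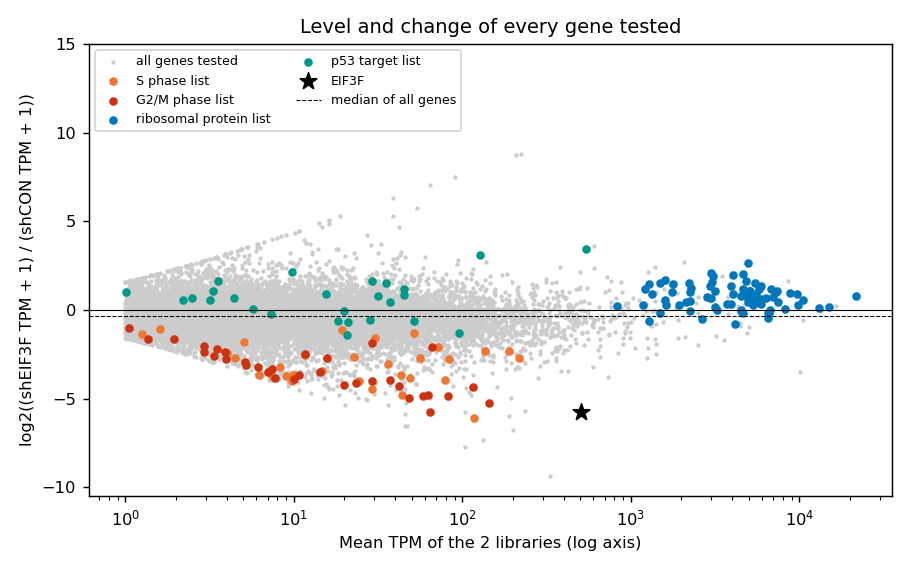
Log2 ratio of shEIF3F over shCON (vertical axis) against the mean TPM of the 2 libraries (horizontal log axis) for 13311 genes, with 4 gene lists and EIF3F marked and the median of all genes (-0.36) as a dashed line. S phase and G2 and M phase genes all lie at -1 or below, ribosomal protein genes range from -0.78 to 2.66, and EIF3F lies at -5.78.

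Transcripts of cytosolic ribosomal proteins were higher while those of ribosome assembly factors were lower. Of the 78 genes for cytosolic ribosomal proteins, 26 were at least 2-fold higher and 0 at least 2-fold lower, and together they held 29.7% of TPM in shCON and 46.1% in shEIF3F. RPL32 stood at 1347 and 8519.5 TPM (log2 ratio 2.66) and RPS6 at 1848 and 7392 TPM (2.0). The list median was 0.70, or 1.06 relative to all genes, above all 10000 random lists, and members ranged from -0.78 to 2.66. Ribosomal protein genes and EEF1A1 have many processed pseudogenes that can share their reads, so single values are uncertain. Other translation factors went both ways. Poly(A)-binding protein PABPC1 was at 469.7 and 2059 TPM (2.13) and elongation factor EEF1A1 at 4214 and 13021 TPM (1.63), whereas EIF4EBP1, the repressor of cap-dependent initiation, was at 524 and 35.3 TPM (-3.86) and EIF4H at 402 and 102 TPM (-1.96). Of 30 such factors 6 were at least 2-fold higher and 7 lower; the median of 0.14 (0.50 relative to all genes) lay at percentile 99.64, but at percentile 91.7 with the GC trend removed. Genes for ribosome biogenesis and the nucleolus had a median of -1.01 (-0.65 relative to all genes, percentile 0.63), with 16 of 31 at least 2-fold lower, among them nucleophosmin NPM1 at 399.5 and 103 TPM (-1.95). That count was 8 after centring and 5 with the GC trend removed. MYC, a transcription factor that drives ribosome biogenesis genes, was lower at 228 and 36.7 TPM (-2.60). Mitochondrial ribosomal protein genes did not stand apart (median -0.47, percentile 62.6, -0.11 relative to all genes). As deposited 17 of 64 were at least 2-fold lower, MRPL24 the most (-2.73), against 8 after centring and 6 with the GC trend removed. Genes of mTOR and translation signalling did not stand apart either (median -0.76, percentile 9.85).

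The androgen-induced kallikreins were lower: KLK4 was at 114 TPM in shCON and 10.8 TPM in shEIF3F (log2 ratio -3.29), KLK2 at 32.6 and 2.5 TPM (-3.26) and KLK3, which encodes prostate-specific antigen, at 9.71 and 1.94 TPM (-1.87). The androgen response list as a whole did not stand apart, with a median of -0.47 over 33 genes (percentile 48.3). As deposited 13 members were at least 2-fold lower and 1 higher, C1orf116 (1.64), chosen after its values were seen; after centring 7 were lower and 7 higher.

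Lineage markers differed in several directions. Luminal epithelial genes were higher, with a median of 0.43 over 13 members (0.79 relative to all genes, percentile 99.72): AGR2 was at 5.57 and 30.2 TPM (log2 ratio 2.25), the adhesion molecule EPCAM at 17.5 and 60.5 TPM (1.73), CD24 had a ratio of 1.49 and CLDN3 of 1.39. The homeobox gene HOXB13, also a luminal member, was at least 2-fold lower at 105 and 44.4 TPM (-1.23), though by less than 2-fold after centring (-0.87). Basal genes, with 6 members measured, also had a higher median of 0.77 (1.13 relative to all genes, percentile 99.47), led by LAMB3 at 0.17 and 2.48 TPM, KRT15 at 1.82 and 5.53 TPM and LAMA3 at 0.48 and 2.24 TPM. The most abundant basal member, the hyaluronan receptor CD44, went the other way, at 32.4 and 17.9 TPM (-0.82). Mesenchymal genes were higher in the median (0.68, 1.04 relative to all genes, percentile 99.98), with CCN2 at 0.05 and 21.6 TPM (4.43), smooth muscle actin ACTA2 at 3.73 and 27.5 TPM (2.59) and fibronectin FN1 at 22.3 and 93.2 TPM (2.02). The epithelial-mesenchymal transition factor SNAI2 went the other way, at 27.5 and 2.53 TPM (-3.01), as did the matrix metalloproteinase MMP14, chosen after its values were seen, at 6.23 and 1.15 TPM (-1.75). Neuroendocrine genes had a lower median of -1.53 over 7 members (-1.17 relative to all genes, percentile 0.42). Synaptophysin SYP was at 11.3 and 2.16 TPM (-1.97), ENO2 at 26.4 and 8.48 TPM (-1.53) and DLL3 at 6.93 and 0.75 TPM (-2.18), whereas chromogranin CHGB was higher, at 0.17 and 2.9 TPM (1.74). With the minimum set at a mean of 5 TPM, the basal and neuroendocrine lists had too few members left to be tested.

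Steroid synthesis and metabolism genes did not stand apart (median -0.14, percentile 78.2, and 0.22 after centring), with 5 of 13 members at least 2-fold higher (UGT2B15, UGT2B17, AKR1C3, AKR1C2 and UGT2B7) and 3 lower: CYP11A1 (-1.20), SRD5A1 (-1.18) and HSD3B1 (-1.03). UGT2B7, CYP11A1, SRD5A1 and HSD3B1 were chosen after their values were seen, and the 3 lower genes were within 2-fold after centring. UGT2B15 was at 3.71 and 61.9 TPM (log2 ratio 3.74) and UGT2B17 at 0.08 and 5.54 TPM (2.60), which both conjugate androgens to glucuronic acid. AKR1C3, which reduces androstenedione to testosterone, was at 16.8 and 56.6 TPM (1.69) and AKR1C2 at 60.6 and 180.5 TPM (1.56). Members of both families are close in sequence, so reads can be split between them and each value is uncertain.

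Genes of glycolysis, ATF4 targets of the integrated stress response and genes of lipid synthesis had lower medians. Glycolysis genes had a median of -1.74 (-1.38 relative to all genes), below all 10000 random lists, with 15 of 20 at least 2-fold lower and 0 higher. The lactate exporter SLC16A3 was at 90.3 and 0.57 TPM (log2 ratio -5.86), PFKFB3 at 34.9 and 1.36 TPM (-3.93) and hexokinase HK1 at 58.5 and 7.06 TPM (-2.88). Targets of ATF4 in the integrated stress response had a median of -1.37 (-1.01 relative to all genes, percentile 0.02), with 18 of 33 at least 2-fold lower. PHGDH, the entry enzyme of serine synthesis, was at 464 and 7.89 TPM (-5.71), mitochondrial PCK2 at 169 and 14.4 TPM (-3.46) and the amino acid transporter SLC7A5 at 82.0 and 4.58 TPM (-3.90). Not all members fell: ATF4 itself was at 569 and 539 TPM (-0.08). After centring 17 members were at least 2-fold lower and 2 higher, DDIT3 (1.21) and SESN2 (1.25). ATF4, DDIT3 and SESN2 were chosen after their values were seen, and whether they share exons is not given here. Fatty acid synthesis genes (median -1.27, -0.91 relative to all genes, percentile 0.52) and cholesterol synthesis genes (median -1.02, -0.66, percentile 1.64) were also lower, with 9 of 16 and 13 of 25 at least 2-fold lower. These counts were 8 and 7 after centring, and 5 and 6 with the GC trend removed. Stearoyl-CoA desaturase SCD was at 155 and 19.2 TPM (-2.95), the lipogenic transcription factor SREBF1 at 122 and 16.5 TPM (-2.81) and mevalonate decarboxylase MVD at 139.8 and 18.7 TPM (-2.84).

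Nuclear genes of the respiratory chain had a median of -0.74 (-0.38 relative to all genes), with 23 of 61 at least 2-fold lower. That count was 18 after centring and 13 with the GC trend removed. The complex I subunits NDUFB3 at 132 and 19.9 TPM (log2 ratio -2.67) and NDUFAB1 at 490.1 and 85.6 TPM (-2.50) were the lowest. The list lay at percentile 3.45 as deposited, inside the limits, and at percentile 0.06 with the GC trend removed. Genes encoded in mitochondrial DNA went both ways around a median of 0.26 (percentile 97.3): MT-ND6 (1.11) and MT-CO1 (1.04) were at least 2-fold higher and MT-ND3 (-1.28) lower, though by less than 2-fold after centring (-0.92). Mitochondrial transcripts held 7.84% of TPM in shCON and 8.24% in shEIF3F. Hypoxia targets (median -0.71, percentile 8.79) and polyamine synthesis genes (median -0.78, percentile 16.2) did not stand apart.

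Antioxidant targets of NRF2 had a higher median of 0.24 over 19 genes (0.60 relative to all genes, percentile 99.46), with 6 at least 2-fold higher and most of the others within 2-fold. GCLM, which encodes the modifier subunit of the enzyme that starts glutathione synthesis, was at 1.56 and 7.84 TPM (log2 ratio 1.79), haem oxygenase HMOX1 at 9.67 and 31.8 TPM (1.62) and the efflux transporter ABCC3 at 23.0 and 75.8 TPM (1.68). Lysosome and autophagy genes had a median of 0.25 (0.61 relative to all genes, percentile 99.88), but most of the 25 members differed by less than 2-fold: the protective protein CTSA (1.54) and LAMP1 (1.12) were higher, and alpha-galactosidase GLA (-2.28), ATG7 (-1.33), CTSD (-1.18) and TFEB (-1.04) lower. LAMP1 and TFEB were chosen after their values were seen, and ATG7, CTSD and TFEB were less than 2-fold lower after centring. Interferon response genes had a lower median of -1.10 over 17 genes (-0.74 relative to all genes, percentile 0.58), with 9 at least 2-fold lower, IFITM1 at 71.6 and 0.78 TPM (-5.35) and IFITM3 at 169 and 41.6 TPM (-2.0) among them, and 1 at least 2-fold higher, ISG20 (1.52), chosen after its values were seen. The median lay inside the limits with the GC trend removed (-0.49, percentile 3.05) and at a mean of 5 TPM or more (-0.21).

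Endoplasmic reticulum chaperones of the unfolded protein response lay inside the limits as deposited (median -0.80, percentile 6.96) and below them with the GC trend removed (-0.62, percentile 0.34), with 10 of 27 at least 2-fold lower, SDF2L1 at 385 and 40.1 TPM (log2 ratio -3.23) and MANF at 611 and 120.0 TPM (-2.34) among them. Splicing factors did the same (median -0.91, percentile 4.43, against -0.73, percentile 0.14), with 11 of 27 at least 2-fold lower, including HNRNPM at 187 and 17.5 TPM (-3.34) and SRSF7 at 94.0 and 23.2 TPM (-1.97). The count of lower splicing factors was 6 after centring and 9 with the GC trend removed. The remaining lists lay inside the limits in both forms. Their medians as deposited were -0.53 for proteasome subunits (percentile 44.6), -0.45 for heat shock genes (48.0), -0.85 for the Notch pathway (4.19), -0.37 for Wnt targets (38.6), -0.75 for NF-kB targets (20.9), -0.40 for MHC class I genes (49.9) and 0.018 for immediate early genes (90.7). The NF-kB median was 0.0054 and the MHC class I median 0.10 with the GC trend removed, and the MHC class I median was also above 0 after rescaling (0.035).

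**Figure D4:**
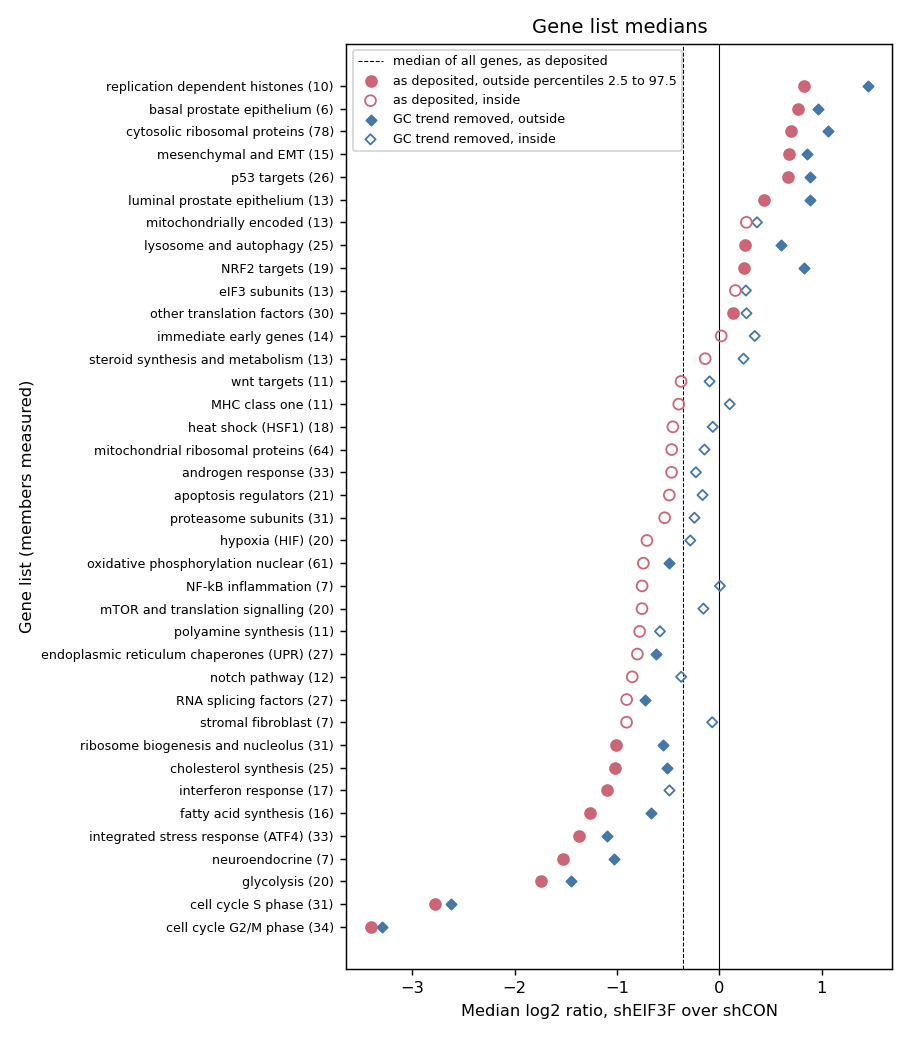
Median log2 ratio of shEIF3F over shCON for gene lists, with the number of measured members in brackets, as deposited (circles) and with the GC trend removed (diamonds). Filled symbols lie outside the central 95% of 10000 matched random lists, and the G2 and M phase list is lowest at -3.40 as deposited.

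No endothelial gene of the list reached a mean of 1 TPM, and the macrophage marker CD68 was at 1.2 and 5.34 TPM. Fibroblast genes did not stand apart over 7 members (median -0.91, percentile 9.08, and -0.070 with the GC trend removed). Of RNAs retained in the nucleus, MALAT1 was at 22.1 and 38.3 TPM, NEAT1 at 36.9 and 57.9 TPM and TUG1 at 7.25 and 8.19 TPM.

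Among single genes with a mean of 5 TPM or more, the 15 lowest ratios included TSPO, the mitochondrial translocator protein, at 376 TPM in shCON and 4.86 TPM in shEIF3F (log2 ratio -6.01), beside EIF3F, TK1, BIRC5, SLC16A3, PHGDH and IFITM1. The lysosomal thiol reductase IFI30 was at 208 TPM in shCON and listed at 0 in shEIF3F, and CCDC144NL was at 264 and 0.65 TPM (-7.32). The 15 highest included the plasma transport protein TTR at 0.14 and 32.2 TPM (4.86), the secreted lectin REG4 at 0.19 and 29.4 TPM (4.67) and ZC3H12B at 0.03 and 21.5 TPM (4.45). Of the 15 highest, 9 share an exon with another gene and 8 were listed at 0 in shCON; the ribosomal protein pseudogene RPL3P4 was listed at 0 in shCON and at 445 TPM in shEIF3F, and RPL39P3 at 666 TPM in shCON and 0 in shEIF3F. Processed pseudogenes differed by 8-fold or more in 15 of 165 cases (9.09%), against 230 of 11292 protein-coding genes (2.04%). A ranking limited to protein-coding genes with no shared exon, chosen after the values were seen, added CRYM, a thyroid hormone-binding protein, at 0.5 and 22.5 TPM (3.97) and the ecto-nucleotidase NT5E at 0.93 and 23.9 TPM (3.69) to the highest, and the mitotic kinase AURKB at 114 and 3.01 TPM (-4.85) and the histone variant H2AFX at 219.9 and 6.93 TPM (-4.80) to the lowest. Of the genes named above, EIF3H, EIF3M, EIF3L, EIF3A, EIF3G, EIF3I, EIF3J, CDKN1A, MDM2, BBC3, RPL32, RPS6, EEF1A1, PABPC1, LAMB3, KRT15, CD44, ACTA2, SYP, CYP11A1, SLC16A3, HK1, SLC7A5, SREBF1, NDUFB3, CTSA, ATG7, CTSD, IFITM1, IFITM3, HNRNPM, CD68, MALAT1, NEAT1, TUG1 and IFI30 share exon sequence with another annotated gene, and their values are uncertain to that extent.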

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

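The alternatives that removed the GC or length trend, or kept only protein-coding genes or genes with no shared exon, were chosen only after the results were seen. No paired analysis was possible because each group had 1 library and the labels give no replicate numbers. EIF3F kept its direction and size, with log2 ratios from -5.86 (pseudocount 0.1) to -5.36 (rescaled). The 1125 genes at least 2-fold higher became 479 with a pseudocount of 5, 619 at a mean of 5 TPM or more, 1958 after centring, 1974 after rescaling, 1758 with the GC trend removed and 554 without genes that share an exon. The 3404 lower genes became 1904 with a pseudocount of 5, 2133 after centring, 2149 after rescaling, 1845 with the GC trend removed and 1612 without shared exons. The pseudocount, the TPM minimum and the shared-exon limit shrink ratios or leave fewer genes to count, centring adds 0.36 to each ratio, and rescaling shifted the ratios by a median of 0.38. The number of lists standing apart was 18 as deposited and ranged from 16 (mean of 5 TPM or more) to 21 (length trend removed). With the GC trend removed, the other translation factors no longer stood apart (0.26) and nor did the interferon response (-0.49), while endoplasmic reticulum chaperones (-0.62), nuclear respiratory chain genes (-0.49) and splicing factors (-0.73) came to stand apart. At a mean of 5 TPM or more the interferon response lay inside the limits (-0.21) and the respiratory chain below them (-0.74), and the basal and neuroendocrine lists had too few members left to be tested, so their standing apart rests in part on genes below 5 TPM. With the length trend removed, the respiratory chain (-0.42), the mitochondrially encoded genes (0.67) and the Notch pathway (-0.57) stood apart, as did the Notch pathway with a pseudocount of 0.1 (-1.31). The cause of these list shifts was not tested. Among named genes, 183 kept their side of 2-fold after centring, 181 after rescaling, 196 with a pseudocount of 0.1 and 177 with the GC trend removed, while 14, 15 and 19 came within 2-fold after centring, rescaling and removal of the GC trend. Of the named genes at least 2-fold higher or lower, JUNB alone changed sign under these 4 alternatives, from -1.09 to 0.061 with the GC trend removed, and the cause was not tested. Unknown depth leaves the precision of genes near 1 TPM open.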

Other observations

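The tests of composition, of fewer dividing cells and of liver and gut genes without the UGT2B family were chosen only after the results were seen, and the reading of the respiratory chain and mitochondrial ribosome tests was set after their values were seen. The GC trend had also been seen before the tests that remove it. Transcripts typical of liver and gut were higher in shEIF3F. Albumin ALB stood at 194 TPM in shCON and 1011 TPM in shEIF3F (log2 ratio 2.38), apolipoprotein APOH at 2.26 and 34.3 TPM (3.44), the intestinal cadherin CDH17 at 4.91 and 29.2 TPM (2.35), TSPAN8 at 36.9 and 157 TPM (2.06) and SPINK1 at 15.3 and 64.1 TPM (2.0). These genes were picked after their values were seen: all 12 picked this way were at least 2-fold higher, with a median of 2.55, which is no independent evidence. UGT2B15, UGT2B17 and AGR2, in fixed lists described above, were among them.

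A hypothesis that a liver and gut gene group was higher as a set was therefore tested on further genes of that kind, listed before their values were seen. Of 28 such genes 11 reached a mean of 1 TPM; 6 of these were at least 2-fold higher and 0 lower, with a median of 1.04. With the GC trend removed the median was 1.06, at percentile 99.9 of matched random lists, in line with that hypothesis. AMBP was at 51.3 and 174 TPM, LGALS4 at 19.6 and 69.2 TPM and MUC13 at 20.7 and 47.2 TPM, whereas VIL1 was at 109.8 and 107 TPM. UGT2B7, also a member of the steroid metabolism list, and UGT2B11 were among the 11, and they are paralogues of genes already seen. Without them, 4 of 9 (AMBP, LGALS4, MUC13 and AFP) were at least 2-fold higher, and the median was 0.42, or 0.71 with the GC trend removed, at percentile 97.7, just past the upper limit. With 1 library per group, whether EIF3F depletion or another difference between the cultures may have set this was not tested.

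The lower level of S and G2 and M phase genes was weighed against technical explanations. A larger part of TPM taken by a few abundant genes would lower the other genes by a common shift. Centring adds 0.36 to every ratio, so the G2 and M phase median had to go from -3.40 to -3.04. That step could not bring it near 0, and shows only that the common shift was small beside this median. The GC bins had medians from 0.072 to -1.15, so removing that trend could not bring a median of -3.40 near 0 either. With the GC trend removed the G2 and M phase median was -3.29. That step also takes out the common shift, so the value compares with the centred median of -3.04, and it lay below that. The trend with GC content therefore accounted for none of this lower median. Fewer dividing cells in the shEIF3F culture stays open as a candidate explanation: the S phase median with the GC trend removed was -2.62, but these genes are the pattern itself, so the value does not decide it. Whether EIF3F loss, another effect of the hairpin or a difference in culture density or timing lay behind the pattern stays open too.

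The higher level of cytosolic ribosomal protein genes was weighed against reads moving from pseudogenes to their parent genes. The summed TPM of 1144 ribosomal protein pseudogenes was 10289 in shCON and 13934 in shEIF3F. That of the 78 parent genes was 295220 and 458508, a gain of 163288. The fall of the pseudogenes was thus -2.23% of the parents' gain, a rise. This outcome was largely fixed in advance, since losing all 10289 TPM would have been only a small part of that gain. The totals show only that the TPM listed for these pseudogenes was too small to supply most of the gain. The list median was 1.06 with the GC trend removed, above the central 95% of random lists. The highest median of any GC bin was 0.072, so removing the trend could hardly have lowered the deposited median of 0.70. The trend with GC content was too small to be the whole cause. Log2 ratios hardly went with transcript length (Spearman's rho 0.0145), so there was little length trend to remove, and the median was 1.04 relative to genes in the same length bins. Length was that of the longest annotated transcript, 2117 bases for RPL32, which need not be the one expressed. The value of 1.04 therefore does not decide on a length bias. An effect of EIF3F depletion may remain as a hypothesis, and a difference between the library preparations was not tested.

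The lower level of glycolysis genes was weighed against GC content bias between the libraries. With the GC trend removed, the glycolysis median lay at percentile 0 of matched random lists, which argues against GC content as the whole cause. The respiratory chain and mitochondrial ribosome medians lay inside the limits as deposited (percentiles 3.45 and 62.6), so those lists showed no departure for GC content to explain, and their percentiles of 0.06 and 24.0 with the GC trend removed decide nothing on it. An effect of EIF3F depletion on the glycolysis list is a hypothesis consistent with these values, with no replicate to test it.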
